A study of Mus musculus with 12 samples.

How the data were processed

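Kidneys of mouse embryos at embryonic day 14.5 were compared between *Bdkrb2* null and wild-type (WT) embryos whose mothers ate food with 5% sodium. *Bdkrb2* encodes the bradykinin B2 receptor. Total RNA of both genotypes was hybridised directly against each other on 12 two-colour Agilent arrays, per the labels' protocols. On 6 arrays the null RNA carried Cy5 and the WT RNA Cy3 (null/WT), and on the other 6 the dyes were exchanged (WT/null). Each orientation had 3 replicates, which the series design text calls biological, and each replicate was hybridised to 2 arrays. Nothing in the labels says whether a sample held 1 embryo or several.

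Spot and background brightness was deposited as median pixel intensity for each dye, and no further normalization had been applied to those columns, per the file headers. The same files held the scanner software's background-subtracted and dye-normalized intensity values and their log10 ratio of Cy5 over Cy3, made with Agilent Feature Extraction 10.5.1.1, per the file headers. The submitters' processing notes name version 6.1 of that software. The series value table held log10 ratios that the authors had turned to null over WT: against the scanner's ratios turned the same way, its columns correlated at 0.998 to 0.999, which settled their direction, and had regression slopes of 1.00 when read as log10, which settled their scale. How the authors chose the entries left blank in it stays unknown. The column medians of that table were 0.00645, 0.000114, 0.00145, -0.00174, -0.00315 and -0.00332 on the null/WT arrays, and -0.000769, -0.000946, -0.00257, -0.00441, -0.0100 and -0.0218 on the WT/null arrays. No column of that table lacked a sample, so 0 were left aside.

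The analysis started from the median spot and local background intensities. The design written before the data were examined had named mean spot signals, which the files used here do not hold. Background was corrected with normexp and an offset of 50 on all spots, and log2 ratios were normalized by loess within each array, with control and outlier spots at weight 0. Control spots were then left out, along with 101 to 262 outlier spots per array. The 43379 remaining spots gave 41174 probes, and spots of one probe were averaged. The 2 arrays of a replicate were averaged, which left 6 values per probe. A probe was tested if it was well above background in the null or in the WT channel on at least 6 of 12 arrays, which kept 22979 probes. Gene names came from the accession of each probe, matched without its version to a RefSeq gene table of assembly GRCm38.p6. A symbol was found for 25097 of the 41174 probes and for 17777 of the tested ones, which covered 12647 genes. The array header names another build (mm9), so positions are given only as chromosome and gene order. A probe without a symbol is unnamed here and is given by its identifier.

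Null over WT was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a term for the dye beside the genotype term. That test equals a comparison of 3 replicates of one orientation with 3 of the other. The Benjamini-Hochberg adjusted p had to be under 0.05 over all tested probes. The dye term itself passed for 3091 probes. The number of arrays limits the precision: the median standard error of a log2 ratio was 0.0506.

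The genes named are *Bdkrb2*, the genes with a symbol other than a clone name past the threshold with the same sign in all 6 replicates (up to 12 per direction, or the 10 with the smallest p where fewer than 5 pass), up to 4 members of each gene list with the smallest p in the list's direction (every measured member of a list under 5 tested genes), and *Xist* and the Y-linked genes. This rule, the 36 gene lists, the tests and most alternatives were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 between genes, using the brightest tested probe of each gene. Camera with an estimated correlation and the rotation test fry were run beside it. Of 141 list genes with several tested probes, 47 had probes of opposite sign, so the choice of probe matters for single members.

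Each slide of 4 arrays held both orientations and both arrays of 1 replicate number. Samples that share a number also deviated together: after removal of each orientation's mean, the pairs of replicates 1, 2 and 3 correlated at 0.587, 0.517 and 0.413. The numbers were therefore treated as pairing the samples through the shared slide, and a fit with the number as a block (3 pairs) was run beside the unpaired one. A block for slide alone would be that same fit. Labels do not say whether the 2 orientations of a number came from the same RNA extracts. If they did, only 3 samples of each genotype were independent, and the unpaired p-values are too small.

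The probe test and the list test were tested on simulated data with the real design and variances over 12647 genes. Without a slide effect, 96 of 100 genes changed by 0.5 on the log2 scale and 100 of 100 changed by 1 were recovered in this comparison, with 18 false calls. With the slide correlation of 0.373 estimated from the arrays, 92 and 98 were recovered with 32 false calls, while the blocked fit recovered 77 and 97 with 9 false calls. All 15 simulated lists of 15 genes shifted by 0.1 were called, and 0 of 15 lists without a shift. These lists were simulated without a slide effect and with genes that varied independently. They therefore do not show how often the list test makes false calls where genes of a list move together. Alternatives covered the block, the dye term, the handling of duplicate arrays, the background correction, the normalization, the authors' value table, the filter on dim probes, the test and each replicate left out. Aquantile normalization leaves log ratios as they are, so scaling between arrays was used as the alternative between arrays.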

Results

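The arrays measured transcript levels in *Bdkrb2* null against WT kidneys at embryonic day 14.5, under gestational salt stress. The 12 arrays made up 6 replicates, 3 per dye orientation, on 3 slides. Between 41.2% and 59.0% of the spots were well above background in Cy3 and between 51.1% and 60.0% in Cy5. The first array of WT/null replicate 3 had the smallest share of Cy3 spots well above background (41.2%). Its median Cy3 signal was nevertheless the highest, at 89 against 35 to 54.5 on the other 11 arrays. Its log2 ratios had an SD of 0.38 against 0.16 to 0.26 on those 11 arrays. Duplicate arrays correlated at 0.711 in that replicate and at 0.824 to 0.923 in the other 5.

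The deleted gene could not serve as a check of the labels. The only *Bdkrb2* probe (A_51_P456753) was well above background in 0 of 12 null channels and in 1 of 12 WT channels, which is 4.17% of all 24 channels (exact binomial 95% interval 0.105% to 21.1%). No fold is given for it. Whether the probe lies in the deleted part of the gene is not given in the sources used here, and at this signal it checks nothing in either case.

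Few transcripts differed between null and WT kidneys past the threshold, and those that did differed in the same direction in every replicate. *Ncapg2*, which encodes a subunit of the condensin II complex, was 4.85-fold higher in null kidneys (log2 2.28 ± 0.05 SE, n = 6 replicates in 3 pairs, limma adjusted p = 1.39e-06). *Tedc1*, which encodes a protein of the tubulin epsilon and delta complex, was 2.25-fold lower (log2 -1.17 ± 0.04, adjusted p = 1.04e-05). With the pairs as a block, *Ncapg2* and *Tedc1* still passed (limma adjusted p = 0.000157 and 0.00156). *Zfp386*, a zinc finger gene, was lower by its probe A_51_P152203 (log2 -0.58 ± 0.06, limma adjusted p = 0.0307). With the pairs as a block that probe did not pass (limma adjusted p = 0.366). Its other probe, A_51_P152211, gave the opposite sign (log2 0.54 ± 0.06, adjusted p = 0.0577), so no direction can be given for this gene. All 3 genes lie on chromosome 12, as does *Bdkrb2*.

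The other 6 probes past the threshold are unnamed. A_52_P521937 was higher by 2.04 ± 0.05 on the log2 scale and A_51_P186703 by 1.53 ± 0.10. A_51_P346874 was higher by 0.71 ± 0.06 and A_52_P40327 by 0.61 ± 0.04. A_51_P516861 stood at -0.80 ± 0.06 and A_52_P324391 at -0.72 ± 0.06. All 9 probes had the same sign in 6 of 6 replicates.

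In total, 9 of 22979 probes passed, 5 higher and 4 lower in null kidneys, and 1610 probes (7.01%) had an unadjusted p under 0.05. With the dye-swap pairs as a block, 4 probes passed (*Ncapg2*, *Tedc1*, A_52_P521937 and A_51_P186703), and 759 (3.30%) had an unadjusted p under 0.05, fewer than the 5% that chance gives. The count was 5 without null/WT replicate 2, 3 without slide 2, 62 without slide 3 and 15 without the first array of WT/null replicate 3. With median centring in place of loess, 5 of 6 calls were higher.

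**Figure D1:**
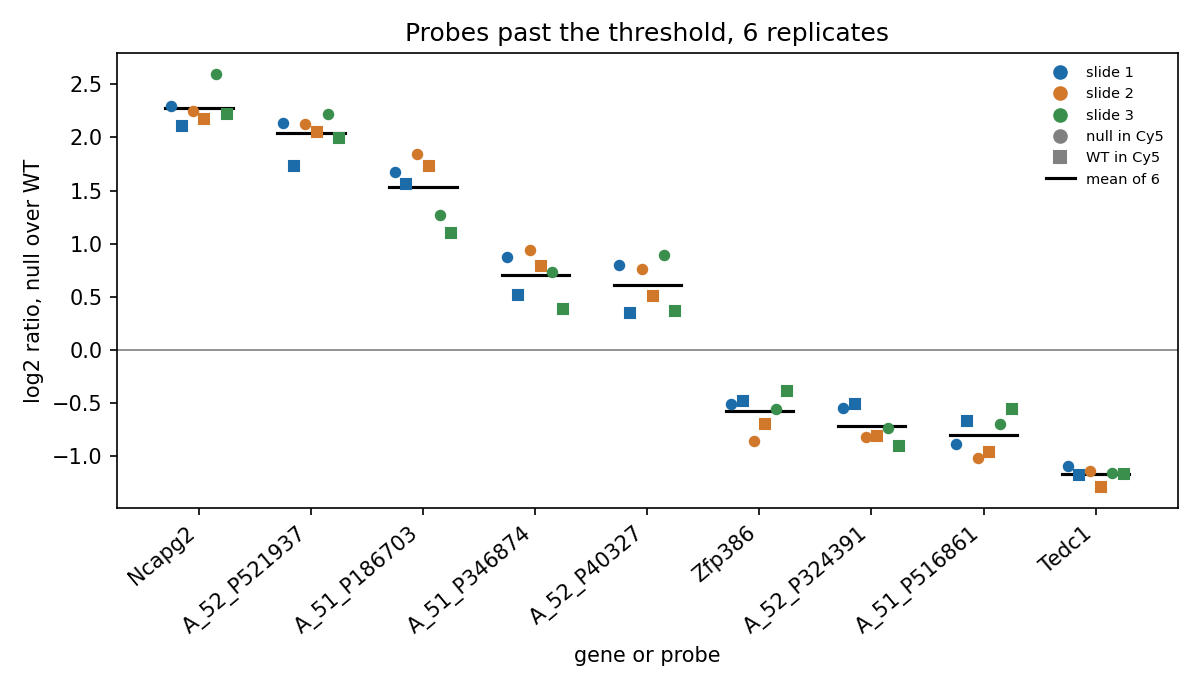
Log2 ratio of null over WT (vertical axis) for the 9 probes past the threshold, in each of the 6 replicates. Circles are null RNA in Cy5, squares WT RNA in Cy5, colours the slide and bars the mean of 6, and all 6 values lie on one side of 0 for each probe, from *Ncapg2* with a mean of 2.28 down to *Tedc1* with a mean of -1.17.

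The genes with the next smallest p did not pass and are given as values. Among those higher in null was *Flt1*, a receptor for VEGF on endothelial cells (log2 0.29 ± 0.04, adjusted p = 0.0778). *Clmn* stood at 0.39 ± 0.05, *Adamts5*, a matrix protease gene, at 0.28 ± 0.04, *Spon2* at 0.27 ± 0.04 and *Dcn*, the gene of the matrix proteoglycan decorin, at 0.35 ± 0.06. *Kdm5c*, an X-linked histone demethylase gene, stood at 0.40 ± 0.06. *Rpl31* stood at 0.61 ± 0.09, while its other probe gave -0.04 ± 0.07. Of the genes with 2 probes, *Adamts5* and *Spon2* had smaller values by the second one, at 0.03 ± 0.04 and 0.11 ± 0.08.

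Among those lower in null were *Wdr60*, which encodes a dynein-2 subunit of cilia (log2 -0.33 ± 0.04, adjusted p = 0.0778), and *Efcab11* (-0.66 ± 0.09, adjusted p = 0.0786). The other probe of *Wdr60* stood at -0.15 ± 0.09. *Serpina1d* stood at -1.33 ± 0.19 and *Serpina1c* at -0.61 ± 0.10. These 2 belong to a family of near-identical alpha-1 antitrypsin genes whose transcripts can cross-hybridise, so neither value can be tied to 1 copy. *Rsrp1* stood at -0.40 ± 0.06, *Car11* at -0.40 ± 0.06, *Timmdc1* at -0.65 ± 0.11 and *Clk1*, a kinase gene of splicing factors, at -0.31 ± 0.05. *Clmn*, *Wdr60*, *Efcab11*, *Serpina1d* and *Serpina1c* also lie on chromosome 12. With each gene ranked by its brightest probe, which leaves *Wdr60* out, 7 of the 20 genes with the smallest p lie there, against 3.31% of tested genes.

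**Figure D2:**
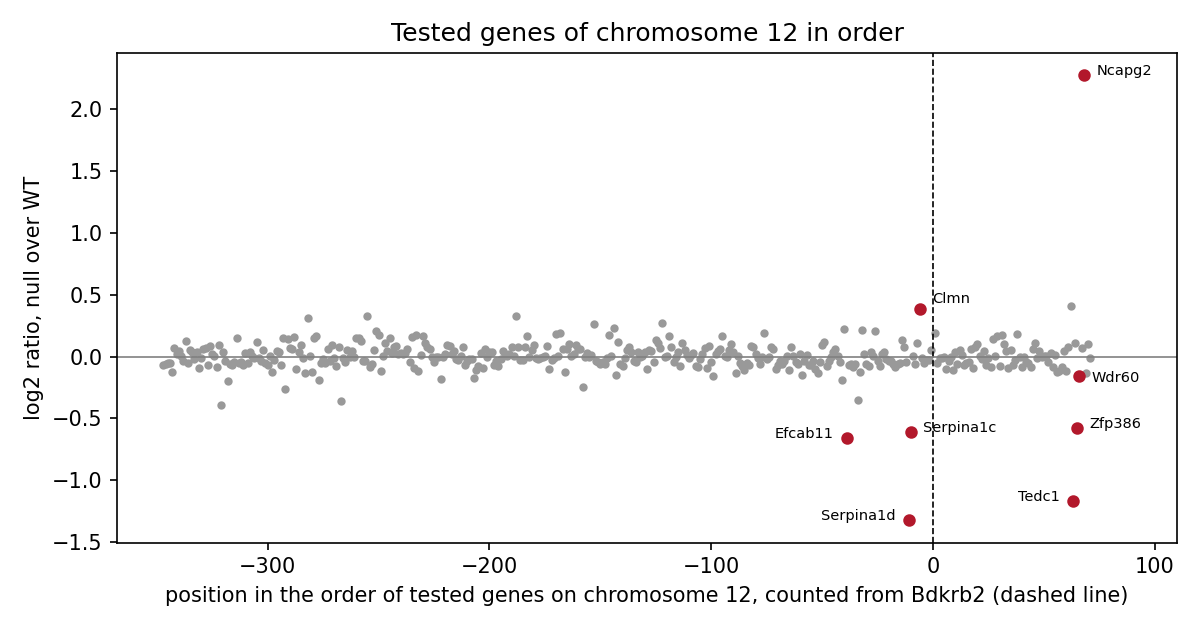
Log2 ratio of null over WT (vertical axis) for the brightest tested probe of each gene of chromosome 12, in gene order counted from *Bdkrb2* (dashed line, horizontal axis). Named genes are in red, with *Ncapg2* 68 tested genes to the right of *Bdkrb2* at 2.28, *Serpina1d* 11 to the left at -1.33, and *Wdr60* drawn with its brightest probe at -0.15.

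Transcripts that tell the sexes apart differed on slides 2 and 3 and not in the same way on slide 1. *Xist*, the X-inactivation transcript of female cells, was well above background in 12 of 12 null channels and in 4 of 12 WT channels, and those 4 were on slide 1. The Y-linked genes *Ddx3y*, *Kdm5d* and *Eif2s3y* were well above background in 0 of 12 null channels and in 8 of 12 WT channels, which were all 4 of slide 2 and all 4 of slide 3. *Xist* gave a log2 ratio of 0.20 on slide 1 and was at least 4.95-fold higher in null on slide 2 and at least 3.43-fold on slide 3. *Ddx3y* was at least 8.13-fold higher in WT on slide 2 and at least 5.18-fold on slide 3, *Kdm5d* at least 4.82-fold and 3.30-fold, and *Eif2s3y* at least 3.36-fold and 2.35-fold. For these bounds, signals under the lowest well-above-background signal of their channel were raised to it before the means were taken. No bound is given for the Y-linked genes on slide 1, where neither genotype was well above background. Over all slides the adjusted p was 0.393 for *Xist*, 0.514 for *Ddx3y*, 0.541 for *Kdm5d* and 0.546 for *Eif2s3y*. *Uty* was not well above background in either genotype. None of these genes passed the threshold, and sex is not given in the labels used here.

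**Figure D3:**
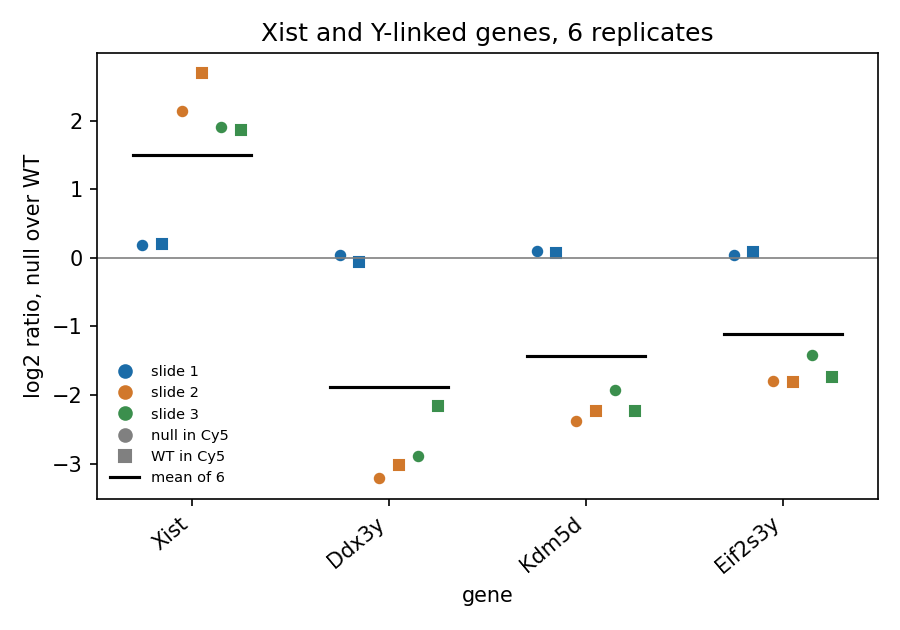
Log2 ratio of null over WT (vertical axis) for *Xist* and 3 Y-linked genes in each of the 6 replicates, with circles for null RNA in Cy5, squares for WT RNA in Cy5, colours for the slide and bars for the mean of 6. Slide 1 lies near 0 for all 4 genes, and slides 2 and 3 lie above 0 for *Xist* and below 0 for the Y-linked genes, where the WT signal of *Xist* and the null signal of the Y-linked genes were not well above background.

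Gene lists fixed in advance shifted more often upward than downward in null kidneys. Of 33 lists tested with camera, 15 passed at an adjusted p under 0.05, with 13 higher and 2 lower in null. Over all genes, 0 members of any list passed. With an estimated correlation 0 lists passed (smallest adjusted p = 0.148), and 5 had an unadjusted p under 0.05. Fry called 7 lists for a shift in one direction (matrix, smooth muscle, endothelium, stroma, cholesterol synthesis, ureteric trunk and early nephron) and 3 for change in either direction. Without WT/null replicate 2 the count was 7, and it was 6 without slide 2. Of 60 named members of the lists past the threshold, the value of 37 fell by over 1.5 times without slide 3, of 2 without slide 2 and of 1 without slide 1.

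Matrix, smooth muscle and vessel genes were higher as groups over all slides together, and slides were not tested one by one. The list medians on slides 1, 2 and 3 were 0.12, 0.10 and 0.17 for matrix, 0.14, 0.13 and 0.35 for smooth muscle and 0.04, 0.04 and 0.14 for endothelium, while single members such as *Cnn1* (0.59, 0.05 and 1.00) and *Kdr* (0.34, 0.02 and 0.07) were uneven. The list of extracellular matrix and TGF-beta response had 11 of 12 tested genes higher (median 0.14, adjusted p = 3.17e-05, and adjusted p = 0.148 with an estimated correlation). Its members *Col1a1* (0.30 ± 0.06), *Col3a1* (0.22 ± 0.05), *Thbs1* (0.20 ± 0.05) and *Postn* (0.17 ± 0.05) encode secreted matrix proteins, and 4 members passed when adjusted over the list alone. Smooth muscle and pericyte genes were higher in 9 of 10 (median 0.17, adjusted p = 3.17e-05, and adjusted p = 0.148 with an estimated correlation). *Cnn1* stood at 0.54 ± 0.14 and *Myh11* at 0.32 ± 0.07, both genes of the contractile apparatus, *Actg2* at 0.19 ± 0.06 and *Pdgfrb* at 0.15 ± 0.05, and 4 passed when adjusted over the list alone. Endothelial genes were higher in 14 of 15 (median 0.07, adjusted p = 0.000120, and adjusted p = 0.191 with an estimated correlation). *Flt1* led them and was the 1 member to pass when adjusted over the list alone, before *Cdh5* (0.14 ± 0.05), *Kdr* (0.14 ± 0.06) and *Tek* (0.08 ± 0.04). Stromal genes were higher in 11 of 15 (median 0.06, adjusted p = 0.00149, and adjusted p = 0.191 with an estimated correlation), with *Lum* at 0.49 ± 0.08, *Penk* at 0.20 ± 0.06 and *Fgf7* at 0.16 ± 0.05 beside *Dcn*, and 4 passed when adjusted over the list alone. Without slide 2 the stromal list had an adjusted p of 0.0674.

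Genes of the kinin and renin-angiotensin system, to which the deleted receptor belongs, were higher in 10 of 12 (median 0.10, adjusted p = 0.00121, and adjusted p = 0.272 with an estimated correlation). *Bdkrb1*, the gene of the other bradykinin receptor, stood at 0.19 ± 0.04 with 0.15, 0.23 and 0.19 on slides 1, 2 and 3. By orientation, replicates 1, 2 and 3 gave 0.06, 0.08 and -0.03 in WT/null and 0.24, 0.37 and 0.42 in null/WT. *Bdkrb1* was dim, well above background in 10 of 12 channels of each genotype. It is also the nearest tested gene on one side of *Bdkrb2* on chromosome 12, among the genes that lie around the deleted one. *Ren1*, the renin gene, stood at 0.86 ± 0.26 and at 1.89 on slide 3, and the angiotensin receptor gene *Agtr1a* at 0.17 ± 0.08 (0.08, -0.02 and 0.43 on slides 1, 2 and 3). The kallikrein gene *Klk1* was well above background in 7 of 12 null and 4 of 12 WT channels, so no ratio is given for it. Of this list 3 members passed when adjusted over the list alone (*Bdkrb1*, *Klk1* and *Ren1*), and without *Klk1*, which is near background, 1 did (*Bdkrb1*). The mean log2 brightness of *Bdkrb1*, 6.64, was no higher than that of *Klk1*, 6.72.

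Proximal and distal tubule genes were higher as groups over all slides together, and highest on slide 3, while the proximal tubule median was below 0 on slide 1. All 13 tested proximal tubule genes were higher (median 0.24, adjusted p = 3.17e-05, and adjusted p = 0.386 with an estimated correlation), but the list median was -0.05, 0.07 and 0.77 on slides 1, 2 and 3, and without slide 3 the adjusted p was 0.611. *Lrp2*, which encodes the endocytic receptor megalin, stood at 0.61 ± 0.10 and was the 1 member to pass when adjusted over the list alone. *Fbp1*, a gluconeogenic enzyme gene, stood at 0.91 ± 0.35 and at -0.08 on slide 1, *Dab2* at 0.16 ± 0.05 and *Slc3a1* at 0.13 ± 0.06. The list of loop of Henle and distal tubule was higher in 6 of 10 (median 0.21, adjusted p = 0.0486, and adjusted p = 0.272 with an estimated correlation). In it, *Slc12a1*, the sodium, potassium and chloride cotransporter gene of the thick ascending limb, stood at 0.62 ± 0.26, *Spp1* at 0.62 ± 0.20, *Sostdc1* at 0.33 ± 0.13 and *Umod*, the uromodulin gene, at 0.32 ± 0.15. These values came largely from slide 3: on slides 1, 2 and 3 *Slc12a1* stood at 0.05, 0.14 and 1.67, *Umod* at -0.01, 0.08 and 0.88, *Spp1* at 0.07, 0.42 and 1.39 and *Sostdc1* at 0.12, 0.06 and 0.81, and the list median was 0.05, 0.07 and 0.37. Ureteric trunk and collecting duct genes were higher in 9 of 13 (median 0.11, adjusted p = 0.0302, and adjusted p = 0.272 with an estimated correlation), with the water channel genes *Aqp3* at 0.49 ± 0.14 (0.17, 0.28 and 1.03 on slides 1, 2 and 3) and *Aqp2* at 0.34 ± 0.12 (0.03, 0.21 and 0.79), *Tfcp2l1* at 0.14 ± 0.06 and *Upk3a* at 0.22 ± 0.09. Podocyte genes were higher in 11 of 13 (median 0.05, adjusted p = 0.00866, and adjusted p = 0.272 with an estimated correlation), with *Nphs1*, the nephrin gene, at 0.20 ± 0.08, *Ptpro* at 0.22 ± 0.10, *Synpo* at 0.13 ± 0.05 and *Plce1* at 0.10 ± 0.04. Without slide 2 the adjusted p of these last 3 lists was 0.201, 0.201 and 0.184, and without slide 3 that of the podocyte list was 0.126.

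The lists for skeletal muscle and cartilage, liver, and leukocytes were also higher. Skeletal muscle and cartilage genes were higher in 7 of 8 (median 0.69, adjusted p = 0.000120, and adjusted p = 0.272 with an estimated correlation), with list medians of 0.14, 0.38 and 1.64 on slides 1, 2 and 3. These genes were thus higher on the same slides as the matrix and smooth muscle lists. Its members *Tnnc2* (1.05 ± 0.32), *Myh8* (1.03 ± 0.30), *Acta1* (0.93 ± 0.34) and *Myog* (0.30 ± 0.09) are muscle genes, and 6 members passed when adjusted over the list alone. Liver genes were higher in 5 of 6 (median 0.11, adjusted p = 0.0474, and adjusted p = 0.305 with an estimated correlation), with *Afp* at 0.48 ± 0.25 (-0.07, 0.05 and 1.45 on slides 1, 2 and 3), *Alb* at 0.13 ± 0.06, *Fgb* at 0.12 ± 0.05 and *Trf* at 0.11 ± 0.05. Macrophage and leukocyte genes were higher in 11 of 13 (median 0.06, adjusted p = 0.0474, and adjusted p = 0.405 with an estimated correlation), with *Ptprc* at 0.14 ± 0.08, *C1qc* at 0.13 ± 0.07, *Adgre1* at 0.12 ± 0.06 and *Aif1* at 0.09 ± 0.05. Without slide 3 the adjusted p was 0.611 for the liver list and 0.792 for the macrophage list, and without slide 2 it was 0.201 and 0.220.

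**Figure D4:**
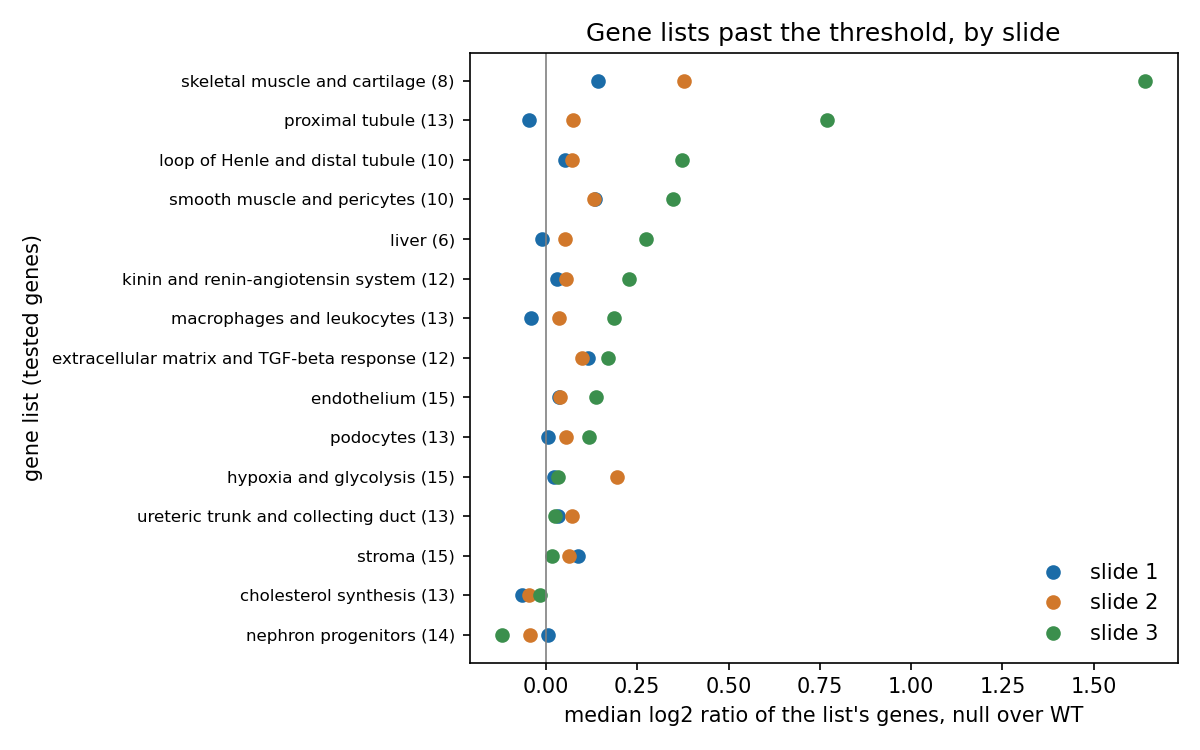
Median log2 ratio of null over WT (horizontal axis) of the tested genes of each list past the threshold, with the number of tested genes in brackets and 1 point per slide. Slide 3 lies farthest to the right for the muscle list (1.64) and the proximal tubule list (0.77), while the 3 slides lie close together for the matrix, stroma and cholesterol synthesis lists.

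Nephron progenitor genes were lower in 11 of 14 (median -0.06, adjusted p = 0.0302, and adjusted p = 0.405 with an estimated correlation), with *Crym* at -0.17 ± 0.06, *Cited1* at -0.10 ± 0.04, *Uncx* at -0.16 ± 0.10 and *Meox1* at -0.06 ± 0.04. Cholesterol synthesis genes were lower in 10 of 13 (median -0.07, adjusted p = 0.00866, and adjusted p = 0.220 with an estimated correlation), with *Lss* at -0.19 ± 0.06, *Fdft1* at -0.16 ± 0.08, *Cyp51* at -0.12 ± 0.05 and *Fdps* at -0.08 ± 0.04. The progenitor list had an adjusted p of 0.508 without slide 3 and 0.184 without slide 2, and the cholesterol list of 0.0577 without slide 1 and 0.0674 without slide 2. With median centring in place of loess the median of all tested probes lay at 0.14, and these lists had medians of 0.12 and 0.13, above 0 but below that shift.

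Hypoxia and glycolysis genes were higher in 12 of 15 (median 0.07, adjusted p = 0.00802, and adjusted p = 0.272 with an estimated correlation), with *Bnip3* at 0.18 ± 0.05, *Ankrd37* at 0.15 ± 0.04, *Ndrg1* at 0.14 ± 0.05 and *Pdk1* at 0.13 ± 0.05. The median was 0.19 on slide 2, and without that slide the adjusted p was 0.648.

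Targets of the transcription factor p53 showed no shift past the threshold: of 19 tested, 10 were higher and 9 lower (median 0.03, adjusted p = 0.259), and 0 passed over all genes or when adjusted over the list alone. *Pmaip1* stood at 0.19 ± 0.06, *Plk2* at 0.17 ± 0.05, *Zmat3* at 0.14 ± 0.08 and *Fas* at 0.12 ± 0.08. The list of neighbours of *Bdkrb2* on chromosome 12, 42 tested genes, had an adjusted p of 0.832 with 17 higher and 25 lower, and 2 passed when adjusted over the list alone. The camera adjusted p was 0.0501 for cell cycle and for immediate early genes, 0.0566 for early nephron genes, 0.0586 for neuronal and neural crest genes and 0.150 for ureteric bud tip genes. It was 0.168 for oxidative stress, 0.194 for sodium transport, 0.262 for imprinted genes and for epithelial junctions and keratins, 0.271 for apoptosis machinery and 0.274 for adrenal and steroidogenic genes. It was 0.314 for oxidative phosphorylation and for erythroid genes, 0.389 for osmotic stress, 0.960 for the Wnt response and 0.978 for the unfolded protein response. In 4 of these 18 lists (epithelial junctions, chromosome 12 neighbours, Wnt response and unfolded protein response) mean, median and test differed in sign. Adjusted over the list alone, 1 member each passed of the immediate early, adrenal and erythroid lists, and 0 of the cholesterol, progenitor, hypoxia, podocyte, liver, macrophage, ureteric trunk and distal tubule lists. The lists of Y-linked genes and of X inactivation had 3 and 1 tested genes, all past the threshold when adjusted over the list alone, and were too small for a list test. The gonad list had 3 tested genes, too few for a test: *Dhh* stood at 0.09 ± 0.08, *Inha* at -0.04 ± 0.07 and *Inhbb* at -0.01 ± 0.06.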

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

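The tests in this part were chosen after the results were seen, except the splits of the replicates into other groups.

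The 10 ways of splitting 6 replicates into 3 and 3 are too few for a share under 0.05. The real split gave 9 probes and 15 lists past the threshold, with as many in 1 of 10 splits in each case, and the highest other split gave 3 probes and 13 lists. The 3 other splits that part all 3 pairs gave 3, 2 and 0 probes, and 3, 0 and 13 lists.

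The first pattern is the placement of the changed genes on chromosome 12, with *Ncapg2*, *Tedc1* and *Zfp386* 63 to 68 tested genes beyond *Bdkrb2*. A response to the missing receptor that ignores gene position is argued against as the whole cause, since 7 of the 20 genes with the smallest p lie on this chromosome (one-sided Fisher's exact p, by the hypergeometric distribution, 2.19e-06, and 0.000681 with the *Serpina1* pair counted once and multiplied by 21 chromosomes). A stretch of another strain's chromosome, carried along with the targeted allele, may account for it, but its test was not decisive: with named genes left out, 2.82% of 213 genes around *Bdkrb2* had a p under 0.01, against 1.67% elsewhere. That share lay at percentile 93.2 of other stretches and missed the limit set for the test, percentile 95, yet 6 genes are too few to exclude the explanation and the genes it is about were left out. Sequence differences under single probes may also contribute, as the opposite signs of the *Zfp386* probes allow, but probes disagreed in 5 of 5 such genes here and in 73.6% elsewhere (Fisher's exact p = 0.328), so these cannot be told apart with 5 genes.

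The second pattern is the difference in *Xist* and Y-linked genes on slides 2 and 3. A dye label swapped on only some arrays of a slide is argued against, since the ratio of *Xist*, turned by the labels, was above 0 on 8 of 8 arrays of these slides. Labels swapped on all 4 arrays of a slide would leave *Xist* at one sign, so its ratio cannot exclude that. *Ncapg2*, turned the same way, was above 0 on 12 of 12 arrays. Embryos of different sex in the null and WT samples of slides 2 and 3 may account for it: *Kdm6a*, *Eif2s3x* and *Ddx3x*, X-linked genes that escape inactivation, were higher there than on slide 1 by a median of 0.42 on the log2 scale, at percentile 99.96 of 10000 random lists. *Ddx3x* did not take part (-0.03), and *Kdm5c* did (0.39). Sex and genotype cannot be separated on those slides, so genes that differ by sex at this stage remain open as a part of the genotype difference, untested. On slide 1 *Xist* was well above background in both genotypes and the Y-linked genes in neither. The 5 higher called probes still stood at 0.57 to 2.20 there and the 4 lower ones at -1.13 to -0.49. For these 9 probes, that argues against sex as the whole cause. *Kdm5c*, by contrast, stood at 0.20, 0.50 and 0.49 on slides 1, 2 and 3 (probe A_52_P124247).

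The third pattern is the height of tubule and muscle genes on slide 3. For the tubule part, the first array of WT/null replicate 3 is argued against as the cause, since the proximal tubule median was at least 0.66 on each of the other 3 arrays of that slide. Muscle tissue in the null sample is argued against for this part too, since it would not raise transporter genes such as *Slc34a1* (1.30) and *Slc22a6* (1.16). The proximal tubule list lay at percentiles 2.67, 99.6 and 100 of 10000 random lists on slides 1, 2 and 3. Its percentile on slide 3 restates the height that defined this pattern and is no further test. Null kidneys of a later stage than their WT partners on slide 3 may account for the tubule part: the progenitor, ureteric tip and cell cycle lists lay at percentiles 0.88, 0.18 and 2.34 (highest 2.34) there. These lists would also fall if tissue from outside the kidney diluted the null sample of that slide, where the muscle list median was 1.64. Their fall alone therefore does not decide for a later stage. For the muscle part, skeletal muscle in the null sample stays open, as 5 of 8 genes, none of them in another list, were over 1 on the log2 scale (*Myh3* at 2.92, *Acta1* at 2.29), while *Col2a1*, a cartilage gene, stood at -0.55. The muscle list lay at percentiles 99.97, 100 and 100 on slides 1, 2 and 3, so tissue from outside the kidney stays open, untested, for the matrix, smooth muscle and stromal lists as well, though the matrix medians (0.12, 0.10 and 0.17) differed far less between slides than those of muscle (0.14, 0.38 and 1.64).

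Of 133 sets of 6 values, 8 held a replicate that stood apart from the others, and chance gives about 1 in 20. *Fas* stood at 0.64 and *Actg2* at 0.51 in null/WT replicate 3, against 0.14 and 0.16 at most elsewhere. *Fgf7* stood at -0.072 in null/WT replicate 2, against 0.14 or more elsewhere. The matrix list had its highest median, 0.25, and the neuronal and neural crest list its lowest, -0.29, in WT/null replicate 3. In null/WT replicate 3 the list of loop of Henle and distal tubule had its highest median (0.55), the unfolded protein list its highest (0.11) and the stromal list its lowest (-0.073).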

How the results depend on the processing

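Leaving out both orientations of a replicate, or the first array of WT/null replicate 3, were alternatives chosen after seeing the data. The cause of each change below was not tested unless stated. The count of 9 probes became 4 with the replicate block of averaged pairs and 148 with 12 arrays and each replicate as a random effect. It became 17 with scaling between arrays and 15 without the first array of WT/null replicate 3. All 9 were among the 148, the 17 and the 15. With replicates left out it ranged from 3 to 62, and under the other 12 settings from 6 to 13. The replicate block as a random effect gave 9. Scanner ratios and the authors' table each gave 8 probes, 6 of them shared. The count of 15 lists became 0 with an estimated correlation and 7 with fry. It ranged from 6 to 19 with replicates left out, and was 14 with the block of averaged pairs and 13 with the random block. Lists past the threshold kept their call in 8 (macrophages) to 24 (matrix, endothelium and smooth muscle) of 25 settings. With no replicate left out, 1383 named-gene values kept their direction and side of the threshold, 42 newly passed and 21 no longer did. Most of the 1383 belong to probes that passed in neither fit, while the 21 all belong to the 9 probes that passed in the main fit. The share of channels with *Bdkrb2* signal, 4.17%, was 0 on the first arrays alone, 8.33% on the duplicate arrays alone, and ranged from 0 to 6.25% with replicates left out. It was not computed without the first array of WT/null replicate 3. The other remaining settings cannot change it, as no fold was computed. With median centring 7 genes turned above 0: *Cyp51* (0.040), *Fdft1* (0.031), *Fdps* (0.12), *Crym* (0.029), *Cited1* (0.11), *Uncx* (0.0053) and *Meox1* (0.13), where the median of all probes moved to 0.14. With replicates left out *Afp* ranged from -0.0084 to 0.75, *Uncx* from -0.31 to 0.013, *Fas* from -0.0066 to 0.19 and the adjusted p of p53 targets from 0.174 to 0.956, turned in direction in 1 setting each. A block for slide was not run separately, since it is the block of averaged pairs. Signal over background limits *Bdkrb2*, *Uty*, *Klk1*, the null side of the Y-linked genes and the WT side of *Xist* on slides 2 and 3.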

Other observations

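The counts and genes in this part were chosen after the results were seen. Slides 1 and 2 shared differences that slide 3 lacked. Without slide 3, 62 probes passed the threshold (39 higher, 23 lower in null), and all 9 of the probes called on all slides were among them. *Hunk*, a kinase gene, stood at 3.52 and 2.64 on slides 1 and 2 and at 0.02 on slide 3. *Slc40a1*, the iron exporter gene, stood at -2.17, -2.36 and 0.14. *Tmem254a* stood at 1.04, 1.03 and 0.08, *Plac9a* at 1.13, 1.29 and 0.31, and *Pop4* at 0.96, 0.88 and 0.01. The metallothionein genes *Mt1* (-0.27, -0.30 and 1.21) and *Mt2* (-0.37, -0.38 and 1.38) turned on slide 3, as did *Klk1b24*, a kallikrein family gene (-1.15, -0.83 and 1.33). *Ren1* passed without slide 3 at 0.34 ± 0.04 (limma adjusted p = 0.0389), but slide 3 did not lack it (0.38, 0.30 and 1.89 on slides 1, 2 and 3). *Fn1*, the fibronectin gene, passed at 0.32 ± 0.04 (limma adjusted p = 0.0389) and turned on slide 3 (0.30, 0.34 and -0.31). Over all slides *Fn1* stood at 0.11 and did not pass. The difference between slides was not tested.

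Of the 41 named genes among those 62 probes, 9 lie on chromosome 12, which holds 3.31% of tested genes, 8 on chromosome 7 (7.81%), 6 on chromosome 1 (5.57%) and 4 on chromosome 16 (3.04%), while 2 lie on chromosome 11 (8.57%) and 1 on chromosome 2 (8.05%). Their placement was not tested. *Pop4*, *Nomo1*, *Bcl2l12*, *Bcat2*, *Car11*, *Klk1b24* and *Dbp* are among the 8 on chromosome 7. The eighth is the RIKEN clone gene *1600014C10Rik*, whose 2 probes gave opposite signs (-0.57 and 0.39). These values come from 4 replicates on 2 slides, and no explanation was tested for them.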
